A study of Mus musculus with 8 samples.

How the data were processed

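Polyadenylated RNA was sequenced from 8 libraries in 2 experiments, with 2 libraries in each of 4 groups. The first experiment compared wild-type (WT) intestinal organoids with Ctnnb1-ex3 organoids, and the second compared a scrambled short hairpin RNA (sh-scramble) with a short hairpin RNA against Prmt1 (sh-Prmt1). Per the labels, all libraries came from a custom form of Smart-seq2, a method that copies polyadenylated RNA into full-length cDNA and in its standard form keeps no strand information. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates were separate cultures or animals, so p-values of single genes measure the spread between these libraries, which may be technical.

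For the first experiment the authors deposited a table of whole-number counts per mouse gene symbol, with 21757 genes. The submitters' processing notes name the mm10 build, Salmon and DESeq2 without roles or versions; the aligner, the counting tool and the annotation behind this table are not given in the sources used here. No deposited count was below 1, and 861 genes stood at 1 in all 4 libraries. In both groups the ratio of replicate libraries was nearly constant over genes of low count only after 1 was taken away, so that 1 was probably added to every count before deposit; no source states this. The counts were used as deposited, and an alternative took 1 away. No mitochondrial gene is listed in this table.

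For the second experiment the authors deposited, per the file headers, gene-level Salmon output for each library, with estimated counts, TPM (transcript abundance scaled to a fixed total per library) and effective gene lengths. The labels give mouse as the organism and mm10 as the build, but all 60237 gene identifiers in these files are human Ensembl genes and 0 are mouse genes. Symbols were taken from the authors' deposited comparison, which pairs 60236 of the identifiers with a human symbol. The human build, its annotation and the Salmon version are not given in the sources used here. Human sex-linked genes, 208 in number, were left out of every step. The estimated counts were rounded to whole numbers for the count tests.

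The authors also deposited their own comparison of each experiment, with log2 fold changes and adjusted p-values and, for the knockdown, mean TPM per group. Values taken from them are named as the authors' deposited table. The values of the first table followed the log2 ratio of mean CPM computed from the count table (correlation 1 across genes).

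Each experiment was fitted alone with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr, and the two-sided quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05, with no limit on the fold. In what follows, edgeR adjusted p stands for this test and adjustment. The filter left 12976 genes in the first experiment and 18445 in the second. Levels are TMM-scaled CPM (counts relative to library size), given as mean ± SD with n = 2 libraries. TMM assumes that most genes do not change, so every fold is relative to the bulk of genes. The biological coefficient of variation was 0.171 in the genotype experiment and 0.105 in the knockdown experiment. Replicate libraries differed by more than counting noise in every group, with a chi-square per degree of freedom of 3.98 for WT, 10.47 for Ctnnb1-ex3, 31.49 for sh-scramble and 17.25 for sh-Prmt1, and each was kept as 1 replicate.

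Gene lists for pathways, intestinal cell types, intestinal regions and other cell types were fixed, together with the designs, the alternative settings and the naming rule, before the data were examined. The first experiment tested 23 lists. The human symbols of the list members were assigned later, when the knockdown tables turned out to hold human genes, and 21 lists had the 3 tested members needed for a test there. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists (camera adjusted p). Camera asks whether the test statistics of the genes of a list differ on average from those of other genes. The test was repeated with the correlation estimated from the libraries. That form takes its degrees of freedom from the few libraries rather than from the genes, so it has little power here. A call lost in it cannot be put down to the correlation. It was also repeated with fry, whose p-value asks whether the genes of a list move on balance in a single direction and whose mixed p-value asks whether they change in either direction; neither compares a list with other genes. For each list the number of members called is given over all genes tested and adjusted over the list alone.

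The text names genes by a fixed rule. Prmt1, Ctnnb1, Axin2, Lgr5, Cdkn1a and Mki67 are always given. Further named are the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 3, no overlap between the groups, and a symbol that is not a predicted or clone name or a name ending in -ps. From each list that passed camera or had at least 3 called members, the 3 members with the smallest adjusted p are named. Some list members that meet this rule are not reported here. Between the experiments, the 4 genes per pair of directions with the largest smaller fold are named. Any other gene was chosen after its values were seen. Where a group stood at the lowest values of the table, a fold is given as a bound against a floor of 3 counts over that group. Bounds of this kind cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules.

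The experiments were compared over 9549 genes tested in both, matched by symbol without regard to case, with two-sided Fisher's exact tests and with the overlap expected of independent lists. No library is shared between them. Genes are not independent replicates, so the correlation of fold changes carries no p-value. For the same reason the Fisher's exact p-values of overlaps and families may be too small.

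Alternative settings fixed at that time were DESeq2 1.42.0 with its own size factors and filtering, limma-voom, RLE and upper-quartile factors, no filter on low counts, a filter of 50 counts in 2 libraries, a fold limit of log2 1 or 1.5, a replicate block, and each library left out in turn. For the knockdown, effective lengths were also used as an offset, and limma with a trend was run on log2(TPM + 1) and log2(TPM + 0.1) for genes with a TPM of at least 1 in at least 2 libraries; these values understate the change of low genes. Further settings were chosen after seeing the data, namely taking 1 away from each count, an offset following read density in counts per kb, leaving out the genes densest in reads, and using human protein-coding genes only. Transcript lengths for read density came from GENCODE M21 on mm10 and covered 20560 symbols (94.5%). Gene positions are from the same annotation. Families of genes with shared name patterns were also chosen after seeing the data, with 37 tested in the first experiment and 40 in the second.

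The procedure was tested on simulated counts drawn from the libraries' own means, sizes and spread, with genes changed by log2 1 or log2 2 in either direction. In the genotype simulation, over 12716 genes, 67.7% of genes changed by log2 1 and 93% of genes changed by log2 2 were called, and 3.6% of calls were false. In the knockdown simulation, over 17875 genes, these shares were 79%, 92% and 2.8%. With no change simulated, 0 genes were called in either. All 5 changed lists, which held raised genes only, and 0 of 20 unchanged lists were called in each. Genes were drawn independently of each other, and the few changed genes were taken from those of higher mean count. The simulation therefore does not show how the tests behave with correlated genes, with low counts or with many changed genes.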

Results

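Polyadenylated RNA was counted per gene in 2 separate experiments. The genotype experiment used intestinal organoids, which are self-renewing epithelial cultures grown in a gel matrix. In the genotype experiment, 2 WT libraries were compared with 2 Ctnnb1-ex3 libraries. The name Ctnnb1-ex3 is in common use for alleles of the beta-catenin gene that lack exon 3, which encodes the phosphorylation sites that mark the protein for degradation. In the knockdown experiment, 2 libraries with a scrambled hairpin (sh-scramble) were compared with 2 libraries with a hairpin against Prmt1 (sh-Prmt1), the main enzyme for asymmetric dimethylation of arginine. The WT libraries held 4631527 and 2951887 counts and the Ctnnb1-ex3 libraries 6015933 and 3683169. The knockdown libraries were deeper, with 39736404 and 45888287 estimated counts in sh-scramble and 39608249 and 53193449 in sh-Prmt1. Levels are given as CPM, counts relative to library size. A floor of 3 counts corresponded to between 0.499 and 1.016 CPM in the genotype libraries and between 0.0564 and 0.0757 in the knockdown libraries. Floors and the bounds built on them cover counting error only. Per the labels, WT organoids received Wnt3a, R-spondin1, Noggin and EGF, while Ctnnb1-ex3 organoids received only Noggin and EGF, so genotype and medium differed together. The knockdown tables listed human genes under labels that name mouse, and they are reported with human symbols. The tissue and culture behind the knockdown libraries are therefore not established here. Nothing in the labels says that replicates were separate cultures or animals. The p of a single gene therefore measures the spread between these libraries, and that spread may be technical. Camera with its preset correlation and Fisher's exact tests take genes as their units and do not measure that spread. Genes are not independent replicates, so those p-values may be too small.

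The genotype comparison asked which transcripts differed between Ctnnb1-ex3 and WT organoids, and whether Prmt1 was among them. All 13 Wnt feedback and target genes that passed the filter on low counts rose in Ctnnb1-ex3 organoids, with a median log2 fold change of 2.10. Here and in what follows, list counts are over members that passed this filter. Of 15 markers of crypt base columnar stem cells, 14 rose, among them the R-spondin receptor gene Lgr5, which went from 13.8 ± 2.57 to 228 ± 4.03 CPM (mean ± SD, n = 2; edgeR adjusted p = 2.39e-05). Of 15 markers of absorptive enterocytes, 14 fell, with a median log2 fold change of -1.45. Prmt1 rose 3.92-fold, from 10.8 ± 0.905 to 41.8 ± 13.4 CPM (n = 2; log2 fold change 1.97 ± 0.33, SE; edgeR adjusted p = 0.00287).

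Prmt1 lies on mm10 chromosome 7 from 44975989 to 44986568 on the minus strand, and its counts were 44 and 30 in WT and 341 and 126 in Ctnnb1-ex3. Axin2, a scaffold of the beta-catenin destruction complex that is itself a Wnt target (chromosome 11, 108920349 to 108950783, plus strand), rose 10.6-fold from 13.3 ± 0.46 to 142 ± 14.6 CPM (n = 2; edgeR adjusted p = 3.82e-05). Lgr5 (chromosome 10, 115450311 to 115587780, minus strand) rose 16.8-fold. The proliferation marker Mki67 (chromosome 7, 135689784 to 135716361, minus strand) rose 1.79-fold to 448 ± 35 CPM, from 251 ± 14.6 (n = 2; edgeR adjusted p = 0.00684). That call was lost with either WT library left out. The log2 fold change of Mki67 was then 0.87 without WT replicate 1 and 0.76 without WT replicate 2, against 0.84. Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand), fell from 300 ± 37.4 to 187 ± 26.1 CPM (n = 2; log2 fold change -0.68, edgeR adjusted p = 0.0188). Its call was lost with upper-quartile factors (-0.44, adjusted p = 0.0602), with an offset that follows read density (-0.24, adjusted p = 0.0511) and without WT replicate 2 (-0.56, adjusted p = 0.141). Ctnnb1 itself (chromosome 9, 120929216 to 120960507, plus strand) stood at 381 ± 58.2 CPM in WT and 253 ± 50.3 in Ctnnb1-ex3 (n = 2; log2 fold change -0.59, edgeR adjusted p = 0.0504). It passed the test under DESeq2 (adjusted p = 0.0024), limma-voom (adjusted p = 0.0494) and no filter on low counts (adjusted p = 0.0118), with a replicate block (adjusted p = 0.00048) and without Ctnnb1-ex3 replicate 2 (-0.81, adjusted p = 0.0129).

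**Figure D1:**
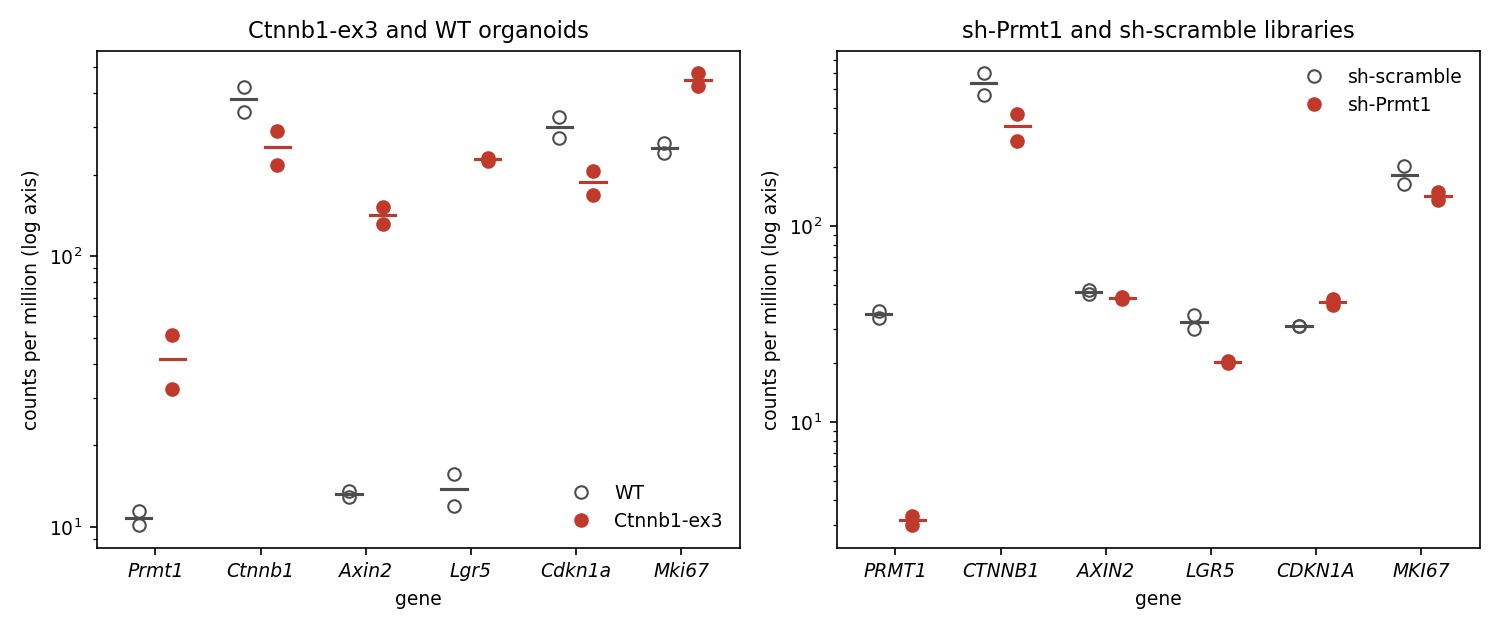
TMM-scaled CPM on a log axis for Prmt1, Ctnnb1, Axin2, Lgr5, Cdkn1a and Mki67 in every library of both experiments; points are libraries and bars are group means of 2 libraries. Lgr5 stood at 13.8 in WT and 228 in Ctnnb1-ex3, and PRMT1 at 35.6 in sh-scramble and 3.17 in sh-Prmt1.

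The Wnt list moved upward as a whole (13 of 13 rose, 13 adjusted over the list alone; camera adjusted p = 7.59e-07, adjusted p = 0.419 with an estimated correlation). The estimated correlation was -0.03, below the preset 0.01, so a higher correlation did not remove this call. Here and for the other lists, that form of the test has little power with 2 libraries per group. Its members Notum, Wif1 and Apcdd1 were under the filter, and Notum had 2 and 3 counts in WT and 3 and 1 in Ctnnb1-ex3. The largest rises in the list included Ascl2, a transcription factor of intestinal stem cells (log2 fold change 4.70), and Nkd1, a feedback inhibitor of Wnt signalling (4.41). The stem cell list gave 14 of 15 over all genes and 14 adjusted over the list alone, with a median of 1.89 (camera adjusted p = 7.59e-07, adjusted p = 0.419 with an estimated correlation). Tnfrsf19, a Wnt-responsive receptor also called Troy, rose 48.9-fold from 1.49 ± 0.496 to 77.9 ± 0.113 CPM (n = 2; edgeR adjusted p = 4.47e-05), and Olfm4, a secreted glycoprotein of crypt base cells, had a log2 fold change of 1.89 (edgeR adjusted p = 0.000401). Prom1 was the member that did not pass, at 0.11 (edgeR adjusted p = 0.604). Lgr5 and Ascl2 belong to both lists.

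The enterocyte list fell as a whole (14 of 15 fell, 14 adjusted over the list alone; camera adjusted p = 7.59e-07, adjusted p = 0.513 with an estimated correlation). Krt20, a keratin of differentiated villus cells, fell 6.15-fold, Mttp, which loads lipid onto apolipoprotein B, fell 7.36-fold, and Alpi, the intestinal alkaline phosphatase of the brush border, fell 13.7-fold from 419 ± 41.1 to 29.6 ± 17.9 CPM (n = 2; edgeR adjusted p = 3e-04). Alpi moved to a log2 fold change of -4.64 without Ctnnb1-ex3 replicate 1, from -3.78. Lct, the lactase gene, had -1.33 and did not pass (edgeR adjusted p = 0.245). Of 8 markers of the proximal small intestine 6 fell, and 6 fell adjusted over the list alone (camera adjusted p = 0.00303, adjusted p = 0.513 with an estimated correlation). These included the duodenal iron reductase gene Cybrd1 (-2.04), the apolipoprotein gene Apoa4 (-2.30) and the retinol carrier gene Rbp2 (-1.39, or -0.76 with an offset that follows read density). The proximal list shares Apoa4, Rbp2, Lct and Fabp1 with the enterocyte list, so its call is not separate from that of the enterocyte list. Of 4 tested distal markers 2 fell, also adjusted over the list alone, namely the ileal bile acid carrier Fabp6 and the ileal bile acid transporter Slc10a2 (-2.13), and the list did not pass (camera adjusted p = 0.144). It passed with fry (adjusted p = 0.0207), with no filter on low counts (adjusted p = 0.0123), without WT replicate 1 (adjusted p = 0.0188) and without WT replicate 2 (adjusted p = 0.0152).

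Markers of rarer cell types rose in part. Of 9 tuft cell markers 5 rose (6 adjusted over the list alone; camera adjusted p = 0.00289, adjusted p = 0.513 with an estimated correlation), among them the cation channel gene Trpm5 (log2 fold change 2.33), the lineage factor gene Pou2f3 (2.26) and the kinase gene Dclk1 (1.94). Of 17 enteroendocrine markers 10 rose, and 10 adjusted over the list alone, with a median of 1 (camera adjusted p = 0.0124, adjusted p = 0.513 with an estimated correlation). Neurog3, the transcription factor that specifies this lineage, rose 6.19-fold, and the hormone genes Ghrl (1.92) and Tac1 (1.69) also rose. That list did not pass with fry (adjusted p = 0.0721) or without Ctnnb1-ex3 replicate 2 (camera adjusted p = 0.188). Of 11 Paneth cell markers 6 rose, and 6 adjusted over the list alone, with a median of 0.78 (camera adjusted p = 0.0251, adjusted p = 0.513 with an estimated correlation). These included Mmp7, the protease that activates alpha-defensins (1.19), and the alpha-defensin genes Defa26 (2.56) and Defa22 (2.30), which share sequence with other copies, so that their individual counts are uncertain. Lyz1, the Paneth cell lysozyme gene, stood at 0.05 and did not pass. The Paneth list was not called with fry (adjusted p = 0.104), without WT replicate 1 (adjusted p = 0.0681) or without Ctnnb1-ex3 replicate 2 (adjusted p = 0.188). Of 10 goblet cell markers 3 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.601). The secreted lectin gene Zg16 fell 9.99-fold (log2 fold change -3.32, or -2.7 with an offset that follows read density). The secreted protein gene Clca1 (1.11) and the secretory lineage factor gene Atoh1 (1.30) rose. The goblet median was -0.39, and 0.16 with an offset that follows read density.

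Genes of cell division and ribosome biogenesis rose in part. Of 20 cell cycle genes 12 rose, and 12 adjusted over the list alone, with a median of 0.59 (camera adjusted p = 0.00745, adjusted p = 0.513 with an estimated correlation). The replicative helicase genes Mcm3 and Mcm4 had 1.30 and 0.94, and the spindle checkpoint gene Bub1 had 1.01. The cell cycle list did not pass with fry (adjusted p = 0.062) or without Ctnnb1-ex3 replicate 2 (camera adjusted p = 0.0941). Of 18 ribosome biogenesis genes 13 rose (14 adjusted over the list alone; camera adjusted p = 0.000688, adjusted p = 0.419 with an estimated correlation), among them the nucleolar genes Nolc1 (1.23), Ftsj3 (0.99) and Nop2 (0.85, adjusted p = 0.0559 without WT replicate 2). Of 8 protein arginine methyltransferase genes 3 rose, and 3 adjusted over the list alone, without a call for the list (camera adjusted p = 0.144). Beside Prmt1 these were Carm1, a type I enzyme (1.98, edgeR adjusted p = 0.0101), and Prmt5, the main enzyme for symmetric dimethylation (0.54, edgeR adjusted p = 0.0136). Each of the latter pair was lost when a WT library was left out. Carm1 then had a log2 fold change of 1.83 without WT replicate 1 and 2.07 without WT replicate 2. Prmt5 had 0.49 and 0.55.

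Cholesterol synthesis genes fell: 12 of 19 fell (13 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 0.000155, adjusted p = 0.513 with an estimated correlation; 0.191 with the preset correlation without the genes densest in reads). They included the sterol enzyme genes Sc5d (-1.66) and Sc4mol (-1.29) and the sterol sensor Insig1 (-1.33). Of 19 interferon-stimulated genes 6 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.088). Psmb8, an immunoproteasome subunit, had -2.03, Oasl2 had -3.30 and Oas1a had -1.39, which did not pass without WT replicate 2 (adjusted p = 0.0572). The list passed with upper-quartile factors (adjusted p = 0.0381), no filter (0.0339), the read-density offset (0.00673) and fry (0.0346), and without WT replicate 2 (0.0346). Of 18 p53 target genes 3 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.819). Fas, a death receptor, fell from 76.7 ± 11.7 to 2.63 ± 2.45 CPM (n = 2; log2 fold change -5.05, edgeR adjusted p = 0.000334; -4.15 without Ctnnb1-ex3 replicate 1 and -6.38 without Ctnnb1-ex3 replicate 2), and the apoptosis gene Pmaip1 (-1.48) and the desmosomal gene Perp (-1.12) also fell.

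The remaining lists were not called by camera with the preset correlation. Of 17 fetal-like and regenerative markers 7 rose (7 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.328), among them Ly6a (log2 fold change 2.01), Anxa1 (1.41) and Cyr61 (1.47). Of 9 Notch pathway genes 4 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.236, fry adjusted p = 0.0127). The receptor gene Notch1 (1.27) and its glycosyltransferase gene Lfng (3.33) rose and the ligand gene Jag1 (-1.23) fell. Of 14 stress response genes 2 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.254, fry adjusted p = 0.0346). Dnajb9 (-2.18) and Ddit3 (-1.28) fell and the cystine transporter gene Slc7a11 (1.70) rose. Of 12 immediate early genes 2 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.339). Zfp36 (-1.18) and Dusp1 (-1.36) fell and Nr4a1 (2.76) rose. Of 20 splicing factor and hnRNP genes 1 rose and 1 fell, and 0 passed adjusted over the list alone (camera adjusted p = 0.601). Of 5 sex-linked genes, Eif2s3y (-0.62) and Ddx3y (-0.41) fell, also adjusted over the list alone (camera adjusted p = 0.177). Of the markers of other cell types, 3 of 17 stromal and endothelial markers and 4 of 13 immune and blood markers had enough counts to test, and 0 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.462 for both lists). Lymphocyte markers under the filter on low counts stood apart in Ctnnb1-ex3 replicate 2. There the protease gene Gzma had 110 counts, the leukocyte gene Ptprc 25 and the T cell receptor complex genes Cd3e and Cd3g 14 and 13. In the other libraries Gzma had 1 count, Cd3e and Cd3g at most 2 and Ptprc at most 4.

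Among genes that meet the naming rule, with an average log2 CPM of at least 3, the largest changes included Ly6c1. This gene, a surface antigen, stood at the lowest value of the table in both WT libraries and at 246 and 97 counts in Ctnnb1-ex3, at least 75.6-fold higher. The matrix gene Efemp1 was at least 39.7-fold higher (124 and 56 counts) and Pxdn, a peroxidase that crosslinks collagen, at least 41.6-fold (159 and 30 counts; log2 fold change 5.66, or 4.57 without Ctnnb1-ex3 replicate 1 and 6.25 without Ctnnb1-ex3 replicate 2). Cbs, an enzyme of the transsulfuration pathway, rose 61.9-fold (edgeR adjusted p = 6.44e-05), and the RNA-binding protein gene Rbms3 had a log2 fold change of 5.67 (6.74 without WT replicate 1 and 5.06 without Ctnnb1-ex3 replicate 1). In the other direction, Gsdmc2, a gasdermin, was at least 95.8-fold lower (147 and 43 counts in WT; log2 fold change -6.85, or -6.24 without WT replicate 1). Sprr2f, a cornified envelope protein gene, was at least 74.6-fold lower (23 and 125 counts in WT; log2 fold change -6.88, -7.79 without WT replicate 1, and -4.61 with an adjusted p of 0.0524 without WT replicate 2). Taking 1 away from each count, which leaves these genes at 0 in a whole group, moved Ly6c1 to 10.08, Efemp1 to 9.17, Pxdn to 9.11, Sprr2f to -9.81 and Gsdmc2 to -9.78. Cfhr2, a complement factor H relative with related copies in the genome, fell 106-fold (-6.73, or -7.48 without Ctnnb1-ex3 replicate 1). Fabp6 fell 97.5-fold (-6.61, or -5.90 without Ctnnb1-ex3 replicate 1 and -7.34 without Ctnnb1-ex3 replicate 2). Ocm, a calcium-binding protein gene, had 124 and 37 counts in WT and 2 and 1 in Ctnnb1-ex3.

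Gt-ROSA.26Sor, the noncoding transcript of the Rosa26 locus, fell 74.5-fold, from 659 and 405 counts in WT to 8 and 13 in Ctnnb1-ex3 (edgeR adjusted p = 3.21e-05; log2 fold change -6.22, or -5.51 without Ctnnb1-ex3 replicate 1 and -6.96 without Ctnnb1-ex3 replicate 2). It lies on mm10 chromosome 6 from 113067428 to 113077333 on the minus strand and overlaps the end of Thumpd3 (113046225 to 113068273, plus strand), so that part of its counts is uncertain in a library without strand information. Thumpd3 had a log2 fold change of -0.54 (edgeR adjusted p = 0.0409), and the neighbouring gene Setd5 (113077365 to 113153435, plus strand) had 0.21 (edgeR adjusted p = 0.24).

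Fold changes fell with read density, the counts per kb of transcript: the median log2 ratio of Ctnnb1-ex3 over WT went from 1.03 in the lowest twelfth of genes to -0.23 in the highest, and the same-group replicate ratio also moved with density.

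**Figure D2:**
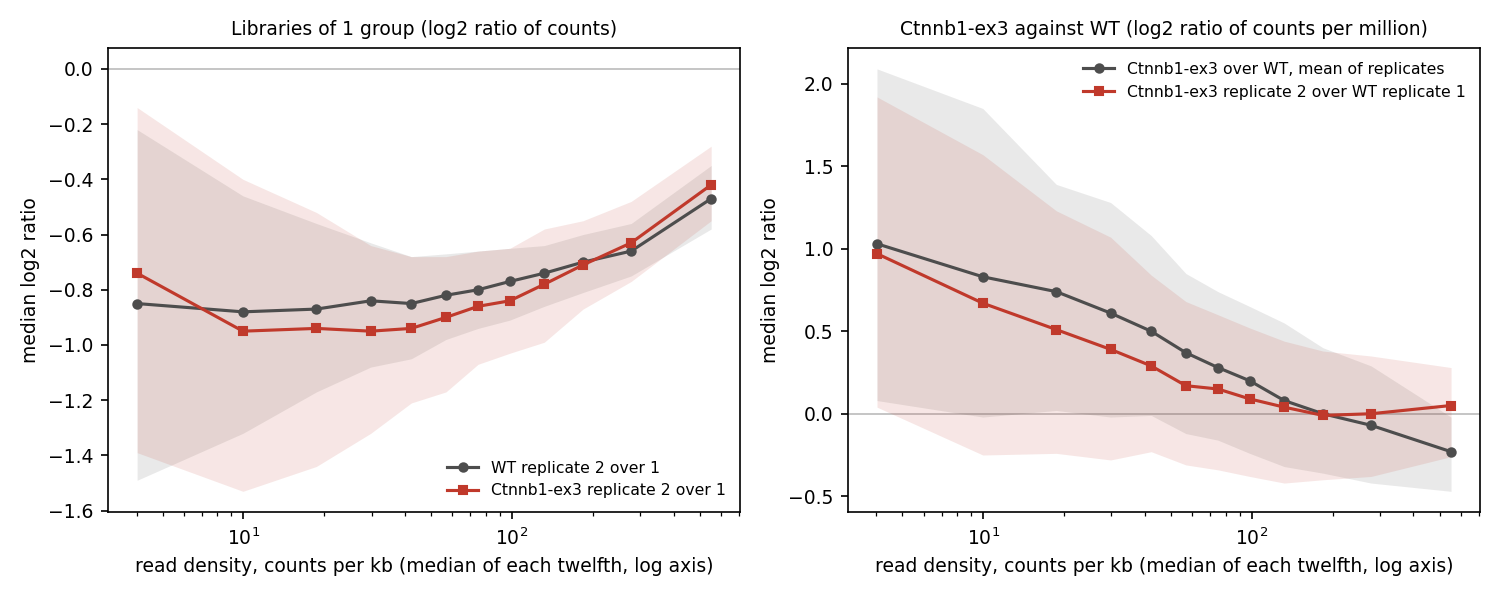
Median log2 ratio between libraries against read density in counts per kb, with genes in twelfths by density and shading between quartiles; replicate 2 over replicate 1 of each group is on the left and Ctnnb1-ex3 over WT on the right. The ratio of replicates rose by 0.38 in WT and 0.32 in Ctnnb1-ex3 from the lowest to the highest twelfth, and the ratio of Ctnnb1-ex3 over WT changed by -1.26.

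In all, 5291 of 12976 genes passed the test, 2637 higher and 2654 lower in Ctnnb1-ex3 (49.8% higher), and 6541 had an unadjusted p under 0.05. With upper-quartile factors 68% of 5477 called genes were higher, after a median shift of 0.238 in log2 fold change, so the balance of directions depends on the scaling. The count was 2960 without WT replicate 1 and 2634 without WT replicate 2. Camera called 10 of 23 lists (11 at an unadjusted p under 0.05). With an estimated correlation 0 were called (1 at an unadjusted p under 0.05), and fry called 11. The authors' deposited table held 1823 higher and 2247 lower genes at an adjusted p under 0.05, and 3928 genes were called both there and here. Sprr2f, called here, did not pass there (authors' deposited adjusted p = 0.398).

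**Figure D3:**
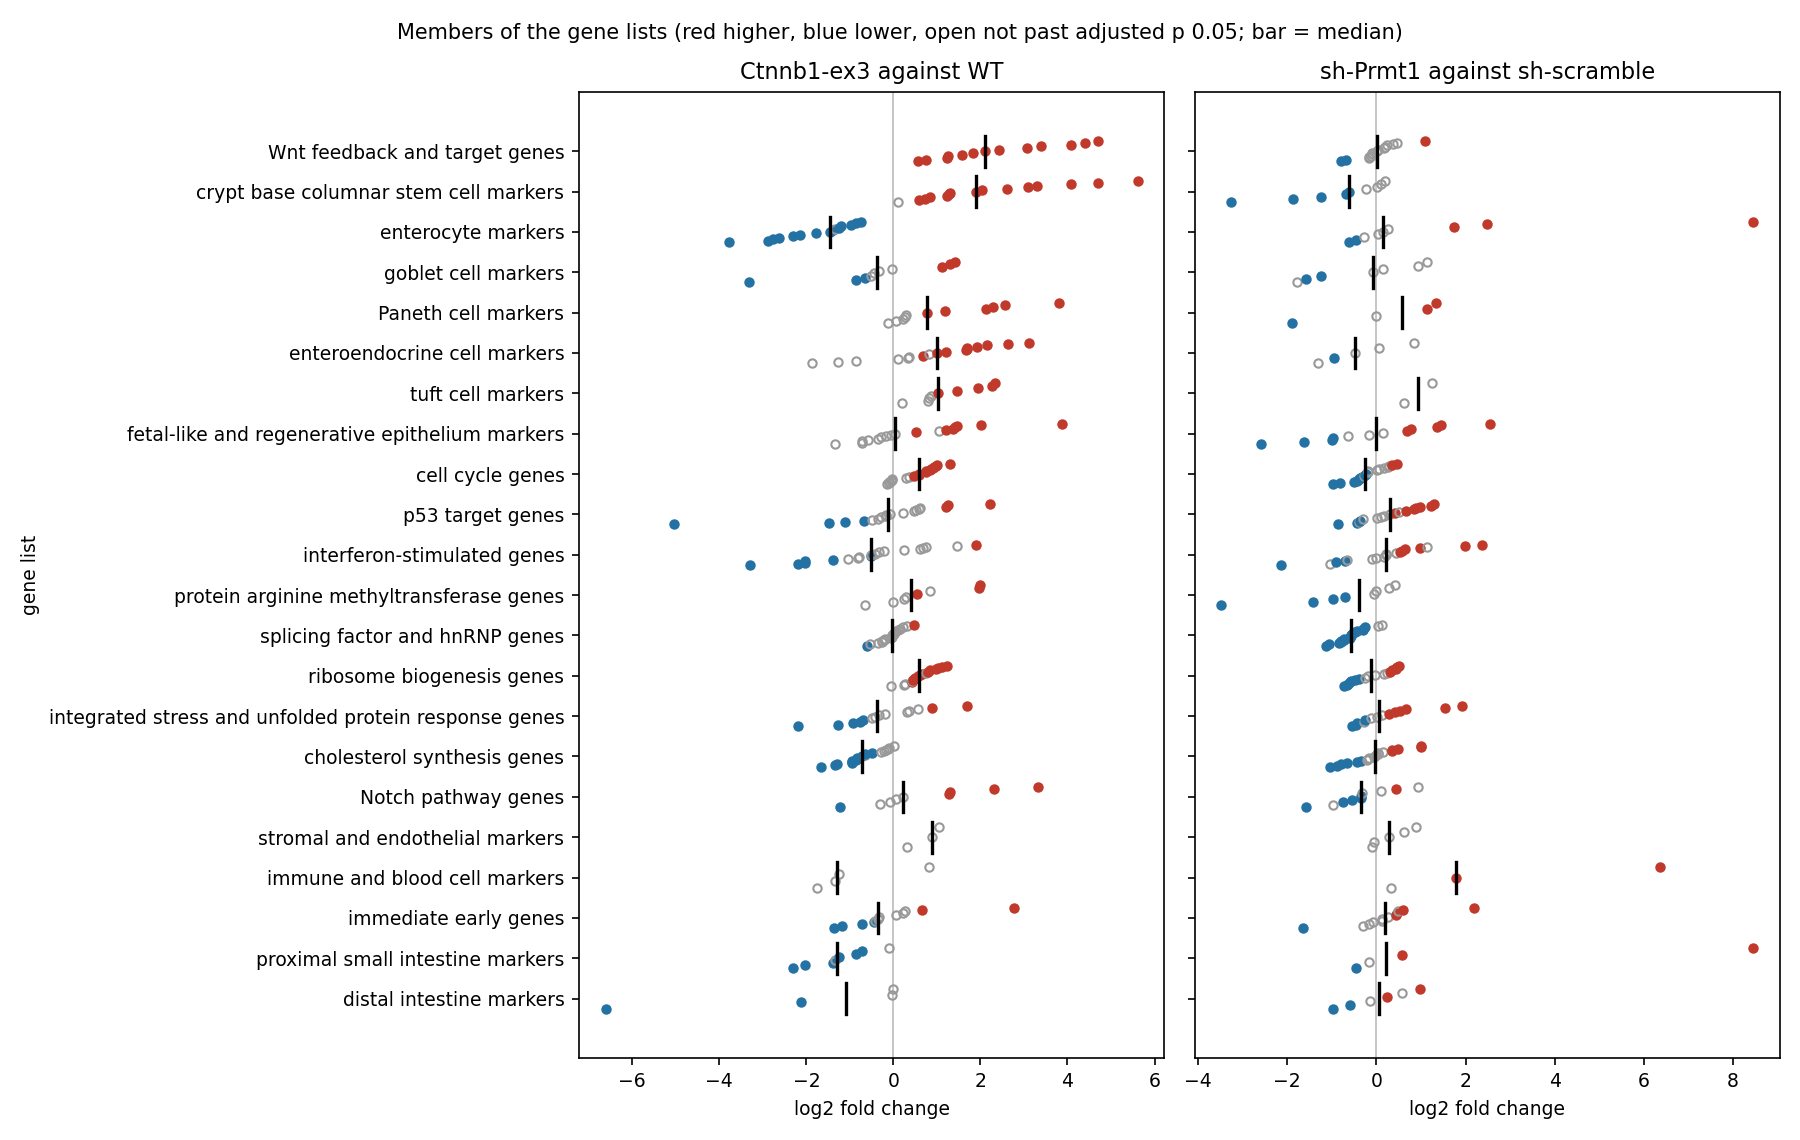
Log2 fold change of each tested member of the gene lists in both experiments, with members that rose in red, members that fell in blue, members that did not pass in open symbols, and a bar at each list's median. The Wnt list had a median of 2.10 in the genotype experiment and 0.01 in the knockdown experiment.

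The knockdown comparison asked which transcripts differed between sh-Prmt1 and sh-scramble libraries. The sample titles name no second hairpin against Prmt1 and no rescue. Effects of the hairpin on other transcripts therefore cannot be told apart from effects of PRMT1 loss. PRMT1 had 1373 and 1451 estimated counts in the sh-scramble libraries and 128 and 190 in the sh-Prmt1 libraries. It fell 11.2-fold, from 35.6 ± 1.99 to 3.17 ± 0.252 CPM (n = 2; log2 fold change -3.48 ± 0.12, SE; edgeR adjusted p = 1.02e-06; -2.86 on log2(TPM + 1), where low values are compressed). Genes of splicing factors and hnRNPs, the proteins that bind and process nascent RNA, fell together: 18 of 20 fell and 0 rose, with a median log2 fold change of -0.56. Of 15 Wnt target genes 1 rose and 2 fell; their median was 0.01, with -0.01 under RLE factors, 0.18 with an effective-length offset and 0.34 over the 13 of them on either TPM scale. EPHB3, a Wnt-responsive receptor tyrosine kinase that helps position crypt cells, fell 9.67-fold, from 78.3 ± 13 to 8.07 ± 0.742 CPM (n = 2; edgeR adjusted p = 1.66e-06; log2 fold change -3.27, or -2.59 on log2(TPM + 1)).

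The splicing factor and hnRNP list was the sole list called by camera (18 of 20 fell, 18 adjusted over the list alone; camera adjusted p = 0.000155, adjusted p = 0.844 with an estimated correlation; fry adjusted p = 0.0188). SRSF2 and SRSF1, both serine and arginine rich splicing factors, had log2 fold changes of -1.07 and -0.72, and HNRNPR had -0.79. Of 8 protein arginine methyltransferase genes 4 fell (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.267, fry adjusted p = 0.0188). Beside PRMT1 they included PRMT3, which methylates a ribosomal protein (-1.43), and PRMT5 (-0.98).

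CTNNB1 fell from 534 ± 95 to 324 ± 71.8 CPM (n = 2; log2 fold change -0.72, edgeR adjusted p = 0.00544), and the call was lost on log2(TPM + 1) (-0.53, adjusted p = 0.113) and log2(TPM + 0.1) (-0.53, adjusted p = 0.118). AXIN2 stood at 46.3 ± 1.77 and 43.1 ± 0.559 (n = 2; log2 fold change -0.10, edgeR adjusted p = 0.361; 0.05 on both TPM scales). LGR5 fell from 32.6 ± 3.93 to 20.3 ± 0.438 (n = 2; -0.68, edgeR adjusted p = 0.000705), and CDKN1A rose from 31 ± 0.163 to 41 ± 2.21 (n = 2; 0.41, edgeR adjusted p = 0.00463). MKI67 fell from 183 ± 27.2 to 142 ± 9.26 (n = 2; -0.36, edgeR adjusted p = 0.0269). It did not pass without sh-scramble replicate 1 (-0.25, adjusted p = 0.0921), without sh-Prmt1 replicate 1 (-0.31, adjusted p = 0.134), with an effective-length offset (adjusted p = 0.176) or on log2(TPM + 1) (adjusted p = 0.488).

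In the Wnt list LEF1, a transcription factor of the pathway, rose (1.10), and LGR5 and the cyclin gene CCND1 (-0.79) fell, the same adjusted over the list alone. CCND1 did not pass with an effective-length offset (-0.33, adjusted p = 0.333) or on log2(TPM + 1) (-0.18, adjusted p = 0.488). Camera gave the Wnt list a downward sign (camera adjusted p = 0.941) while its median, its mean of 0.03 and fry were upward. Of 9 stem cell markers 5 fell (6 adjusted over the list alone; camera adjusted p = 0.151), among them EPHB3, LGR5 and CDCA7, a target of MYC (-1.25). Of 9 enterocyte markers 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.703, fry adjusted p = 0.0188). The sucrase-isomaltase gene SI (2.48, or 3.12 without sh-scramble replicate 1) and the aminopeptidase gene ANPEP (1.74) rose, though both stayed under 3 CPM. RBP2 had 0 reads in both sh-scramble libraries and 61 and 31 in sh-Prmt1, at least 24.5-fold higher. The enterocyte median was 0.15 over 9 genes, and -0.15 over the 5 of them that passed the filter of both TPM scales.

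Secretory and regional markers moved in both directions. Of 7 goblet cell markers ATOH1 (log2 fold change -1.58) and AGR2 (-1.25), a protein disulfide isomerase needed for mucin folding, fell, also adjusted over the list alone (camera adjusted p = 0.658). Of 5 enteroendocrine markers REG4 fell (-0.96), also adjusted over the list alone (camera adjusted p = 0.703). Of 4 Paneth cell markers MMP7 (1.14) and LYZ (1.33) rose and DEFA6 fell (-1.90), the same adjusted over the list alone (camera adjusted p = 0.619, fry adjusted p = 0.0348). LYZ did not pass without sh-Prmt1 replicate 1 (adjusted p = 0.114) or under DESeq2 (adjusted p = 0.0753). DEFA6 did not pass without sh-scramble replicate 2 (adjusted p = 0.153) or sh-Prmt1 replicate 2 (-1.07, adjusted p = 0.141), and had -3.64 without sh-Prmt1 replicate 1. DEFA6 also did not pass with an effective-length offset (adjusted p = 0.106) or on log2(TPM + 1) (-0.79, adjusted p = 0.0809) and log2(TPM + 0.1) (adjusted p = 0.11). Of 6 distal markers 2 rose and 2 fell. FABP6 (0.98) and HOXA9 (0.24, a member named after its value was seen) rose, and the posterior patterning gene HOXB9 (-0.98) fell (3 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.987). The median of the distal list was 0.05 while fry was downward. Of 4 proximal markers RBP2 and CYBRD1 (0.57) rose and the fatty acid carrier gene FABP1 (-0.46) fell, the same adjusted over the list alone (camera adjusted p = 0.703). On log2(TPM + 1) FABP1 (-0.25, adjusted p = 0.21) did not pass.

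Of 20 cell cycle genes 2 rose and 10 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.267). The nucleotide synthesis gene RRM2 (-0.97) and the replication clamp gene PCNA (-0.81) fell and the mitotic kinase gene PLK1 (0.47) rose. Of 17 p53 target genes 7 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.291, fry adjusted p = 0.0307). ZMAT3 (1.30) and PERP (0.67) rose and RPS27L (-0.87) fell. Of 18 interferon-stimulated genes 6 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.601). ISG15 (0.97) and OAS1 (0.58) rose. Of 14 stress response genes 6 rose and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.703), with ATF3 (1.93, or 1.01 on log2(TPM + 1)), CHAC1 (1.54) and DNAJB9 (0.52) higher. Of 12 immediate early genes 4 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.601). BTG2 (2.20) and KLF6 (0.60) rose and EGR1 (-1.64, or -0.81 on log2(TPM + 1)) fell. Of 10 Notch pathway genes 1 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.300, fry adjusted p = 0.0348). The falls included HES1 (-0.74), NRARP (-0.54, or -0.36 with an adjusted p of 0.0501 on log2(TPM + 1)) and ATOH1 (-0.98 on log2(TPM + 1)).

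Of 20 cholesterol synthesis genes 5 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.703). DHCR7 (0.99) rose and FDFT1 (-0.79) fell. Of 18 ribosome biogenesis genes 6 rose and 7 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.703), with WDR12 (-0.63), NOP58 (-0.72) and NOP56 (-0.59) lower. Of 12 fetal-like markers 5 rose and 4 fell, the same adjusted over the list alone (camera adjusted p = 0.905). The alarmin gene IL33 (-2.59, or -1.43 on log2(TPM + 1)) and the annexin genes ANXA3 (-1.62) and ANXA1 (-0.98) fell. Of 5 tested stromal and endothelial markers 0 passed, over all genes or adjusted over the list alone (camera adjusted p = 0.703). Of 3 tested immune and blood markers the lysosomal gene CD68 (1.79) and the globin gene HBB rose, also adjusted over the list alone (camera adjusted p = 0.151, fry adjusted p = 0.0188). HBB had 2 and 1 reads in sh-scramble and 116 and 222 in sh-Prmt1. Of the tuft cell markers 2 were tested, too few for a list test, and 0 passed, over all genes or adjusted over the list alone.

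Among genes that meet the naming rule, with an average log2 CPM of at least 3, the largest rises were in ABCC2, an efflux pump for conjugated compounds (13.9-fold, from 1.43 ± 0.117 to 19.8 ± 0.672 CPM, n = 2; edgeR adjusted p = 1.55e-06), TM4SF20 (9.22-fold) and PDGFA, a growth factor gene (8.98-fold). MT1G, a metallothionein with near-identical copies that make its own level uncertain, rose 7.58-fold, MEIS2, a homeobox gene, rose 6.64-fold, and CTSA, a lysosomal carboxypeptidase gene, rose 6.21-fold. In the same set, the largest falls after PRMT1 and EPHB3 were in DCK, the deoxycytidine kinase gene (7.13-fold, from 59.9 ± 6.77 to 8.35 ± 2.06 CPM, n = 2; edgeR adjusted p = 5.22e-06), FAIM2 (6.19-fold), IL33 (6.01-fold) and CMTM4 (5.97-fold). On log2(TPM + 1) the log2 fold changes were 2.08 for ABCC2, 2.57 for TM4SF20, 2.30 for PDGFA, 2.12 for MEIS2 and -2.22 for DCK, and ABCC2 had 3.21 on log2(TPM + 0.1).

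In all, 7559 of 18445 genes passed the test, 3794 higher and 3765 lower in sh-Prmt1 (50.2% higher). On log2(TPM + 1) 64.4% of called genes were higher, after a median shift of 0.165, and on log2(TPM + 0.1) 64.7%, after a shift of 0.184. The TPM settings changed the library scaling, the filter, the length correction and the test together, and tested 12565 genes. DESeq2, with its own size factors and filtering, tilted the other way, with 41.2% of called genes higher. Settings that changed the scaling or the length correction alone gave 48.1% with RLE factors, 51.6% with upper-quartile factors and 51.2% with an effective-length offset. Camera called 1 of 21 lists (3 at an unadjusted p under 0.05) and 4 with no filter on low counts, the added lists being those of cell cycle (adjusted p = 0.0238), protein arginine methyltransferase (adjusted p = 0.0454) and immune and blood cell genes (adjusted p = 0.0303). With an estimated correlation 0 were called (0 at an unadjusted p under 0.05), and fry called 7. The authors' deposited table held 2498 higher and 3408 lower genes at an adjusted p under 0.05. In both tests 5420 genes were called, 5409 of them in the same direction. Genes named above as called that did not pass in the authors' deposited table included ANPEP, CYBRD1, DNAJB9, LYZ, CCND1 and DEFA6. Their log2 fold changes there were 0.89, 0.26, 0.30, 0.64, -0.22 and -0.83.

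The last comparison asked whether genes that differed in Ctnnb1-ex3 organoids were those that changed on PRMT1 knockdown. It sets mouse organoids against libraries that hold human genes and whose material is not established, with genes matched by symbol. Genes lower in Ctnnb1-ex3 were higher in sh-Prmt1 more often than independent lists would give (629 genes against 549.7; odds ratio 1.28, two-sided Fisher's exact p = 1e-05, adjusted p = 4e-05 over 4 direction pairs). Genes higher in Ctnnb1-ex3 were also higher in sh-Prmt1 less often (436 against 501.5; odds ratio 0.79, Fisher's exact p = 0.000122, adjusted p = 0.000244). That deficit did not pass without WT replicate 2 (194 against 215, Fisher's exact adjusted p = 0.178) or with no filter on low counts (320 against 332.9, Fisher's exact adjusted p = 0.42). The pairs that were lower in sh-Prmt1 did not pass: 458 genes against 487.5 were higher in Ctnnb1-ex3 (p = 0.0833, adjusted p = 0.111) and 556 against 534.4 were lower (p = 0.222, adjusted p = 0.222, Fisher's exact tests). Both depended on the setting. The pair lower in both passed as an excess under DESeq2 (adjusted p = 5.59e-05), a replicate block (759 against 690.2, adjusted p = 0.00052), no filter (adjusted p = 8.08e-16), without sh-scramble replicate 1 (adjusted p = 0.00253) and without Ctnnb1-ex3 replicate 2 (adjusted p = 0.00397, all Fisher's exact tests). The pair higher in Ctnnb1-ex3 and lower in sh-Prmt1 passed as an excess with no filter (odds ratio 1.21, adjusted p = 0.00283) and the read-density offset (odds ratio 1.18, adjusted p = 0.00411, Fisher's exact tests). It passed as a deficit under limma-voom (0.87, adjusted p = 0.0307), without sh-scramble replicate 1 (0.82, adjusted p = 0.00106), without Ctnnb1-ex3 replicate 1 (0.85, adjusted p = 0.00503) and without Ctnnb1-ex3 replicate 2 (0.86, adjusted p = 0.00397, all Fisher's exact tests). With a log2 fold change of at least 1 in both, the first excess grew (102 against 41.5; odds ratio 3.09, Fisher's exact p = 2.08e-18, adjusted p = 8.32e-18), and the pair higher in both turned to an excess (86 against 58.7; odds ratio 1.6, Fisher's exact p = 0.00026, adjusted p = 0.00052).

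Of 9549 genes tested in both, 2079 were called in both and 992 of these moved in the same direction (47.7%; odds ratio 0.84, 95% interval 0.70 to 1.01, Fisher's exact p = 0.0567). This association passed without WT replicate 2 (odds ratio 0.75, p = 0.0287), without sh-scramble replicate 2 (0.72, p = 0.000568), without sh-Prmt1 replicate 1 (0.72, p = 0.00105) and without sh-Prmt1 replicate 2 (0.81, p = 0.0311, all Fisher's exact tests). Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of -0.022 and a Spearman correlation of -0.006.

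Genes with large opposite changes included EPHB3 (3.09 in Ctnnb1-ex3 and -3.27 in sh-Prmt1), PRMT1 (1.97 and -3.48), the receptor tyrosine kinase gene KIT (2.22 and -1.78) and TACC1 (1.77 and -2.02). In the reverse sense ABCC2 (-1.87 and 3.80), SDCBP2 (-1.93 and 2.54), the actin-severing protein gene SCIN (-2.59 and 2.09) and the heme oxygenase gene HMOX1 (-2.45 and 1.66) were lower in Ctnnb1-ex3 and higher in sh-Prmt1. Higher in both were SNN (2.95 and 1.58), the tubulin gene TUBB2A (1.45 and 2.47), RAB15 (1.44 and 1.64) and the metalloproteinase inhibitor gene TIMP3 (4.16 and 1.36). Lower in both were ARL1 (-1.59 and -1.5), MTMR6 (-1.75 and -1.29), the fatty acid elongase gene ELOVL6 (-1.27 and -2.33, the latter -1.54 with an effective-length offset) and OPN3 (-2.77 and -1.26). In the genotype experiment Tubb2a did not pass without either WT library (adjusted p = 0.114 for each) nor Hmox1 without WT replicate 2 (adjusted p = 0.146). There Snn had 3.55 without WT replicate 1, and Scin had -3.24 without Ctnnb1-ex3 replicate 1. In the knockdown SCIN had 2.77 with an effective-length offset, and KIT had -1.17 and ELOVL6 -1.03 on log2(TPM + 1).

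**Figure D4:**
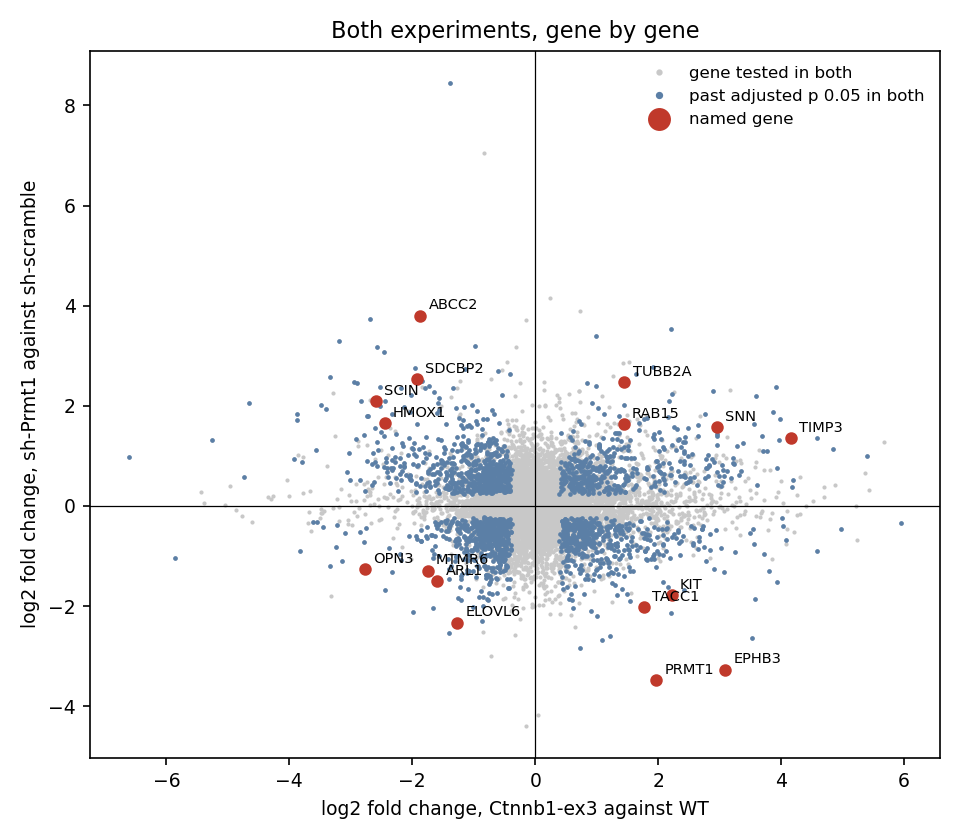
Log2 fold change of Ctnnb1-ex3 over WT on the horizontal axis against log2 fold change of sh-Prmt1 over sh-scramble on the vertical axis, 1 point per gene tested in both experiments, with 16 genes named. EPHB3 lies at 3.09 and -3.27 and ABCC2 at -1.87 and 3.80, while the Pearson correlation across all 9549 genes was -0.022.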

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

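Besides Prmt1, 154 single-gene and 44 single-list results were followed through the alternatives that covered them. Each pair of 1 result with 1 alternative was counted, so a result counts many times. For single genes 2138 pairs kept direction and side of the threshold. For lists 528 pairs kept their side of the threshold. Uncalled lists in these pairs could change direction, as the knockdown Wnt list did with fry. The call was lost in 38 single-gene and 19 single-list pairs and gained in 5 and 20. The log2 fold change of Prmt1 kept its call in all 29 alternatives. A library left out leaves an arm with a lone sample, which is then assumed to vary like the others. Depth limits genes under a few CPM in the genotype libraries, where the floor lies up to 1.016. For the genotype comparison the count of called genes ran from 2634 to 7757 with libraries left out, against 5291, and was 2853 with a log2 fold change of at least 1 and 1773 with at least 1.5, by construction. For the knockdown it ran from 5811 to 6893, against 7559, and was 2264 and 975 with these limits. Lists called with an estimated correlation, a form of the test with little power here, numbered 0 in each experiment. In the knockdown fry called 7 (4 upward, 3 downward) and no filter gave 4 (1 upward, 3 downward), against 1. The odds ratio of the overlap, 0.84, ran from 0.72 to 0.95 with libraries left out and passed with a log2 fold change of at least 1 (0.53, Fisher's exact p = 0.0161), DESeq2 (0.75, p = 0.00604), no filter (0.81, p = 0.0387), at least 50 counts in 2 libraries (0.83, p = 0.0438), the read-density offset (0.63, p = 1.35e-07) and without the genes densest in reads (0.77, p = 0.0156), the last pair chosen after seeing the data. The correlation of fold changes turned to 0.047 with no filter and ran from -0.032 to 0.021 with libraries left out, against -0.022, and the log2 fold change of AXIN2 to 0.05 on log2(TPM + 1) and 0.05 on log2(TPM + 0.1). Except for the fold limits, the cause was not tested.

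The replicate numbers of the labels were used as a replicate block as an alternative, giving 6484 and 7091 called genes, 10 and 1 called lists and an odds ratio of 0.90; the block gained the call of Ctnnb1 and that of the genes lower in both experiments (Fisher's exact adjusted p = 0.00052). Deviations of same-numbered libraries correlated across genes at 0.07 in the genotype and -0.05 in the knockdown experiment, so no crossed block was run.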

Other observations

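All families and technical tests described here were chosen after the results were seen. In Ctnnb1-ex3 organoids, several families of detoxifying genes were lower. Of 37 cytochrome P450 genes, which oxidise drugs, bile acids and lipids, 27 fell and 3 rose, with a median log2 fold change of -1.99 (Fisher's exact p = 8.76e-12, adjusted p = 2.16e-10 over 74 tests); Cyp3a11 had -3.58, while Cyp2e1 rose (2.37). Of 10 UDP-glucuronosyltransferase genes 8 fell (median -2.46, adjusted p = 0.000678), among them Ugt2b5 (-5.57). Of 19 glutathione S-transferase genes 13 fell (median -0.95, adjusted p = 8.76e-05), and of 12 aldo-keto reductase genes 9 fell (median -1.13, adjusted p = 0.000611), among them Akr1b7 (-4.27). Members of these families share sequence, so the counts of single copies are uncertain. Of 242 solute carrier genes 101 fell and 45 rose (adjusted p = 1.07e-12 for the falls), among them the glucose transporter gene Slc2a2 (-4.11), while of 36 ATP-binding cassette transporter genes 12 fell and 7 rose (adjusted p = 0.166 for the falls). Of 11 cathepsin genes 8 fell and 1, Ctsf, rose (3.71), and of 18 V-ATPase genes 10 fell and 1 rose (adjusted p = 0.00146 and 0.00536 for the falls). Of 26 kinesin genes 14 rose and 2 fell (median 0.83, adjusted p = 0.00097), among them Kif15 (1.13). Of 13 ephrin and Eph receptor genes 7 rose and 3 fell, with Efnb2 lower (-2.55). That family passed Fisher's exact test for the rises (adjusted p = 0.0272) but not camera (camera adjusted p = 0.0984). None of the 37 families was called by camera with an estimated correlation, a form with little power here, where the smallest adjusted p was 0.596.

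In sh-Prmt1 libraries, genes of the core splicing machinery outside the fixed list were also lower. Of 37 small nuclear ribonucleoprotein and LSM genes 21 fell and 2 rose, with a median of -0.60 (Fisher's exact p = 1.28e-06, adjusted p = 4.52e-05 over 80 tests); LSM5 had -2.03 and SNRPE -1.85, and pseudogene copies of SNRPE and SNRPG share reads with their parents. Of 82 cytosolic ribosomal protein genes 35 fell and 10 rose (median -0.18, Fisher's exact adjusted p = 0.000111). Of 91 mitochondrial ribosomal protein genes 35 fell and 14 rose (median -0.16, Fisher's exact adjusted p = 0.000792, camera adjusted p = 0.0635). On log2(TPM + 1) these medians were 0.03 and 0.01, the latter over 87 genes. Of 15 HLA genes 11 rose and 0 fell (median 1.17, adjusted p = 0.000218), with reads shared between copies. Of 12 mucin genes 7 rose and 0 fell (median 1.08, adjusted p = 0.0408), among them the membrane mucin genes MUC17 (3.69) and MUC13 (1.54). Of 8 metallothionein genes, which bind zinc and copper and are near-identical copies, 5 rose and 0 fell (Fisher's exact adjusted p = 0.0783, camera adjusted p = 0.0234). Of 248 solute carrier genes 80 rose and 41 fell (Fisher's exact adjusted p = 0.000218 for the rises, camera adjusted p = 0.167). Among the rises was the manganese exporter gene SLC30A10 (3.30). With an estimated correlation, a form with little power here, the smallest camera adjusted p over the 40 families was 0.554.

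Fold changes of Ctnnb1-ex3 over WT fell as read density rose, by 1.26 in log2 ratio from the lowest to the highest twelfth of genes. Libraries of the same group, which share genotype and medium, also changed in ratio with density, by at least 0.32 in both groups, which is consistent with a levelling-off of the deposited counts at high density. Depth of the Ctnnb1-ex3 libraries as the whole cause is argued against, since the shallower Ctnnb1-ex3 replicate 2 over the deeper WT replicate 1 still changed by -0.92 (95% interval -1 to -0.82). How much of the trend comes from levelling-off was not shown, and a difference due to genotype or medium stays open as untested. With an offset that follows density 5137 genes were called, 4083 of them shared with the 5291.

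More genes had at least 1 read in sh-Prmt1 (38082 and 37847) than in sh-scramble (31437 and 32401). Depth is argued against: with all libraries thinned to 39606774 reads, the lower sh-Prmt1 library still had 4335 more genes than the higher sh-scramble library. A trace of stromal or immune cells cannot be told apart from the rest, since 6 of their abundant transcripts stayed at or under 0.581 RPM, reads relative to library size and near the floor, while 5 of these 6 were higher in both sh-Prmt1 libraries than in both sh-scramble libraries. Reads on 850 genes with olfactory receptor symbols were 36 and 37.5 RPM in sh-scramble and 72 and 58.1 in sh-Prmt1. The ratio was at least 1.55 between libraries of the groups. These genes were assumed, and not shown, to be silent in this material. Only under that assumption does the ratio fit more reads from DNA or low-level background. An effect of the knockdown on silent genes stays open as untested; genes with a mean under 10 reads held at most 0.171% of the reads of any library.

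The knockdown tables hold human gene identifiers under labels that name mouse. S100P and CEACAM6, human genes whose symbols are not among the mouse gene names, stood at 208 TPM or more in every library. This argues against mouse reads quantified on human transcripts, and against mouse identifiers exchanged for human ones after counting, since either would leave these genes without reads. Human material under a mouse label remains the open explanation, and no biological explanation was tested.

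HBB had 2, 1, 116 and 222 reads in the 4 knockdown libraries while HBA1 had 0, 6, 8 and 10 and HBA2 had 0 in each. Across genes, the Spearman correlation of log2 fold change with average expression was -0.41 in the genotype and -0.14 in the knockdown experiment.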
